A study of Mus musculus with 54 samples.

How the data were processed

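Liver RNA from male wild-type mice was made into libraries with a stranded messenger RNA kit, per the labels' protocols. The series has 54 samples in 14 groups of diet and treatment. One table was given, with 6 libraries: 3 of mice on a high sucrose diet for 1 week (HS) and 3 of mice on that diet given DAS at 200 mg per kg by gavage 3 h before death (HS DAS). Columns were matched to samples by the library names in the labels, and each group was taken from the sample titles. The other 48 samples were not analysed here.

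The deposited values are a signal in the form of gene counts normalized by the authors with DESeq2, whose version is not given, on the mouse build mm10, per the submitters' processing notes. The aligner, the counting tool and the annotation are not given in the sources used here. In the deposited table the median ratio of each library to the gene-wise geometric mean was 1.005 in all 6 columns, so the libraries had been scaled together. The values are fractional. Steps of 1 read could be found for only part of the low genes: between 47% and 55.5% of the low values per library were whole multiples of the step within 0.05, so whole reads could not be recovered. Factors that differ from gene to gene and fractional counts of reads shared between genes would both give this, and they were not told apart. The counts that the planned quasi-likelihood test needs were thus missing, and the planned fallback for normalized values, limma-trend, was used. The most common step put the depth at 8800000, 8440000 and 8560000 reads in HS replicates 1 to 3 and at 11470000, 9430000 and 9570000 in HS DAS replicates 1 to 3, an estimate that rests on 84 to 187 genes per library.

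The table lists 24972 genes, 8977 of them at 0 in all libraries. In 9 symbols a comma stood in place of a point and was changed back. A further 13 symbols had become dates in September; they were left as they stand, since a date does not give back the symbol with certainty, and the 9 of them that were tested belong to no list and are not named. Mitochondrially encoded genes are not listed in it. Of the symbols, 98% were found in GENCODE's annotation of GRCm38, which is mm10, and 99.1% of the tested genes had a transcript length there; coordinates are from that annotation and count from 1. No pair of libraries held identical values, and every pair differed by more than sampling noise (chi-square per degree of freedom from 21.8 to 157.5).

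Genes with a mean of at least 10 over the 6 libraries were tested, 11413 in all. Differences are HS DAS minus HS on log2(value + 1), a scale that understates the change of low genes. The test was limma-trend (limma 3.58.1 in R 4.3.3) with group as the only term and Benjamini-Hochberg adjustment, so every adjusted p of a gene is from that model. Before the data were examined, 44 lists of pathway genes and cell type markers had been written. The 36 with at least 3 tested genes entered camera with a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. The other 8 lists, among them the mitochondrially encoded subunits and markers of T cells, B cells, pancreas, fat and muscle, had too few tested genes. Some genes belong to several lists, so the lists are not independent. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

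The rule for named genes, also written before the data were examined, had 4 parts: the genes with the largest rise and fall among those past an adjusted p of 0.05 with a mean CPM of at least 1, groups that did not overlap and a symbol that names a known gene, of which there were 0; from each list with members past that threshold those with the lowest adjusted p, and from each called list without such members the 2 with the lowest p; Cth, Cbs, Mpst, Sqor, Ethe1, Nqo1, Hmox1, Gclc, Cyp2b10, Cyp2e1, Cyp1a1, Fasn and Pck1 whatever their result; and, with fewer than 5 genes past the threshold, the 5 with the lowest p. Dbp, Arntl, Npas2, Nfil3, Tef, Per3, Usp2, Nr1d1, Ciart, Mt1, Mup16, Osgin1 and Hspa1a fall outside it and were chosen after their values were seen.

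The steps were tested on simulated data with the means and spread of these libraries and with noise drawn independently for each gene. The simulated lists thus held uncorrelated genes and do not test the preset correlation. Estimated correlations within the real lists reached 0.95. The noise took each gene's moderated spread and held no structure shared between genes, so the recovery given next may exceed that in the real data. For HS DAS against HS over 11413 genes, 23.9% of genes changed by 1 log2 unit, 88.1% of those changed by 2 and 97% of those changed by 3 were recovered at an adjusted p of 0.05, with 14 false calls, and all 5 shifted lists of 30 were called with 0 false calls among the rest. Alternatives were equal totals, upper-quartile scaling, no filter, a filter at a mean of 5 CPM, pseudocounts of 0.1 and 10, the replicate number as a block, leaving out each library, and a fold threshold. Added after the data were seen were an adjusted p of 0.10, robust moderation, no trend, array weights, removal of each library's trend on transcript length or GC content (splines with 4 degrees of freedom), and leaving out HS replicate 3 and HS DAS replicate 2 together.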

Results

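Liver messenger RNA was sequenced from male wild-type mice in a study that, by its title, asked how hydrogen sulfide made without enzymes bears on lifespan and health. The values used here came from mice fed a high sucrose diet (HS) for 1 week, with 3 libraries from mice without a listed treatment and 3 from mice given DAS by oral gavage at 200 mg per kg of body weight 3 h before they were killed (HS DAS). The labels give DAS only as an abbreviation. They do not say whether the HS mice received a gavage without the compound, so the gavage and the compound cannot be separated in this comparison. They also give no times of death. A difference in the time of day between the groups therefore cannot be separated from either, for any gene or list below. The other 48 of the 54 samples of the series, on standard, high fat and combined diets and with other treatments, were not analysed here. The values are normalized counts of 24972 genes, whose totals per library ran from 8678060 to 10166569. Steps among the low values pointed to between 8440000 and 11470000 assigned reads per library, a depth at which a gene with a mean near 10 rests on about that many reads. By this estimate every HS DAS library (at least 9430000 reads) was deeper than every HS library (at most 8800000). Depth before scaling thus also differed with the group. The labels number the replicates without naming the animals, so the adjusted p-values measure the spread between these samples.

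The comparison asks which liver transcripts differed 3 h after DAS in mice on the sucrose diet. By a test with a preset correlation between genes, lists of Nrf2 targets, ATF4 and amino acid response, immediate early, cholesterol synthesis, lipogenesis and glucocorticoid-responsive genes were called higher in HS DAS, and endoplasmic reticulum chaperones lower. With an estimated correlation none of these 7 lists was called (adjusted p from 0.217 to 0.337), and no single gene passed an adjusted p of 0.05. Chka, which encodes choline kinase alpha, averaged 887.7 ± 235 normalized counts in HS DAS and 165 ± 37 in HS (SD, n = 3 each), 5.32-fold higher on the log2(value + 1) scale. Thbd, the gene of thrombomodulin, averaged 111.9 ± 36.1 against 17.5 ± 3.3. Trp53inp1, a p53-induced stress gene, averaged 1834 ± 498 against 472.7 ± 78.9. In each of these genes all 3 HS DAS libraries lay above all 3 HS libraries. They were named for having the lowest p (limma adjusted p = 0.0646 each), a choice that favours groups without overlap.

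By limma-trend with Benjamini-Hochberg adjustment over 11413 genes, 0 genes passed an adjusted p of 0.05. At an unadjusted p under 0.05 there were 1033 genes, 663 higher and 370 lower in HS DAS, where chance alone gives about 571 on average. Genes do not vary independently, and splits of the libraries that mixed the groups gave from 41 to 3127 such genes. The genes with the lowest p, Chka, Gdf15, Srxn1, Thbd and Trp53inp1, shared an adjusted p of 0.0646, with log2 differences of 2.41 (SE 0.25), 2.74 (SE 0.32), 1.76 (SE 0.21), 2.57 (SE 0.31) and 1.93 (SE 0.24). Counts under the adjusted threshold moved with the libraries used: 3 genes without HS replicate 1, 1 without HS DAS replicate 2 and 5 without HS DAS replicate 3. The count at an unadjusted p under 0.05 was 627 without HS replicate 2, 574 without HS DAS replicate 1 and 1620 without HS DAS replicate 2. With the trend on transcript length removed from each library, an alternative added after the data were seen, 12 genes passed. The groups did not overlap in 15.1% of genes, where chance gives 10% on average.

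**Figure D1:**
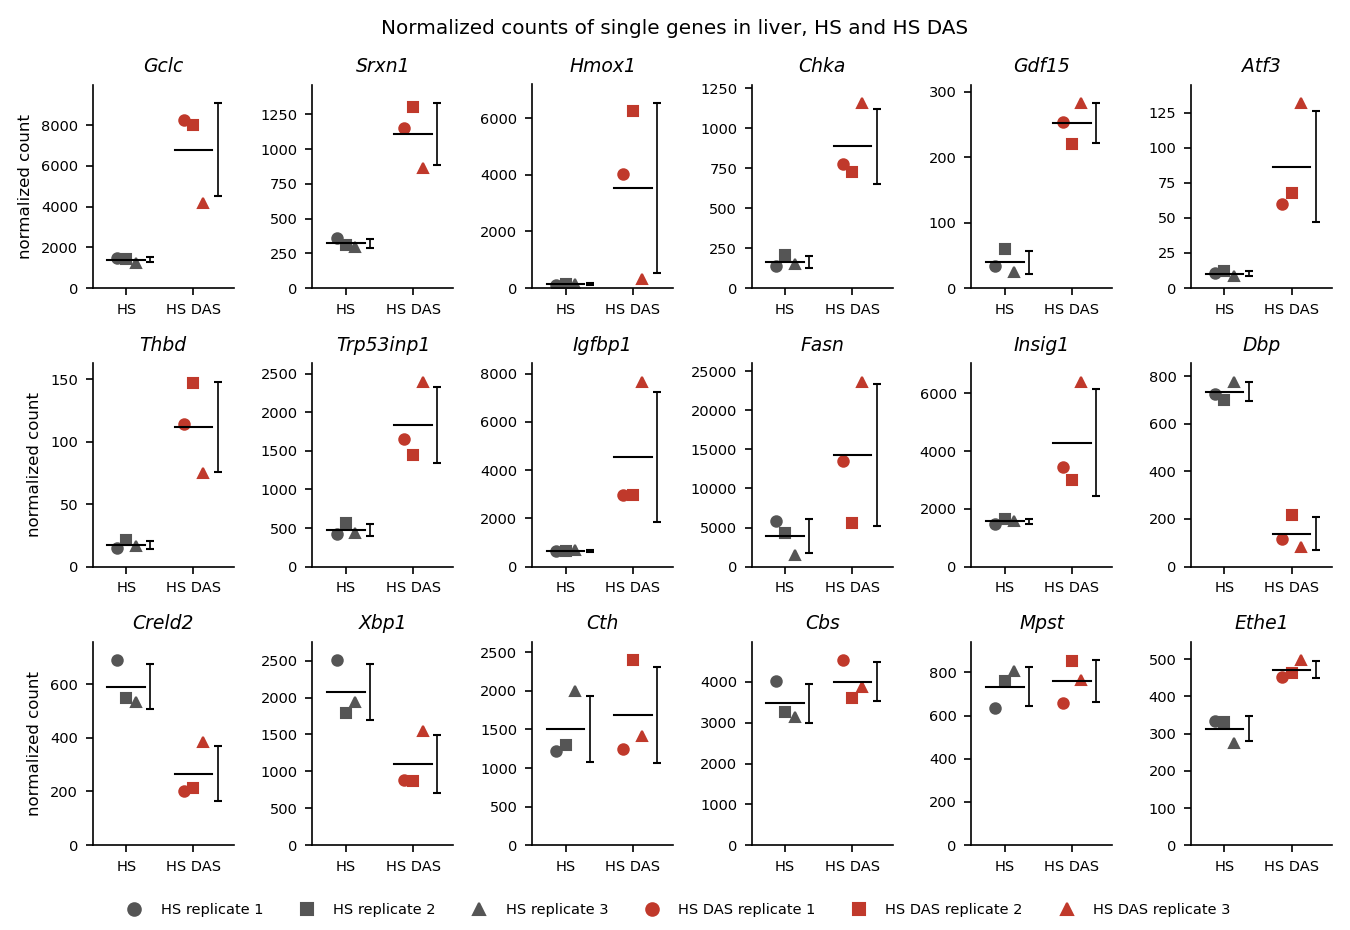
Normalized counts of 18 genes in each liver library; the vertical axis of each panel is linear and starts at 0, symbols mark the replicate, horizontal lines the group mean and bars the SD (n = 3). Gclc, Srxn1, Chka, Gdf15, Atf3, Thbd, Trp53inp1 and Igfbp1 lie higher in every HS DAS library than in any HS library and Dbp lower, while the hydrogen sulfide enzymes Cth, Cbs and Mpst overlap between the groups.

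Of 36 gene lists written before the data were examined and tested with limma's camera at a preset correlation of 0.01, 19 were called at an adjusted p of 0.05, 14 higher and 5 lower in HS DAS. With an estimated correlation between genes 0 of the 36 were called, the lowest adjusted p being 0.217. That version was not run on simulated data, so its power with these libraries is not known. Splits of the 6 libraries that mixed the groups also called from 4 to 18 lists at the preset correlation. The fry test called 0 for a shift in one direction (lowest adjusted p = 0.0587) and 8 for change in either direction. Those 8 included the Nrf2, ATF4, immediate early and glucocorticoid lists, but not those of cholesterol synthesis, lipogenesis or chaperones. No member of any list passed when adjusted over all genes. Markers of sinusoidal endothelium, stellate cells and Kupffer cells were among the lists called higher. The log2 differences correlated with transcript length across 11308 genes (Spearman's rho = 0.26, genes not being independent replicates).

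**Figure D2:**
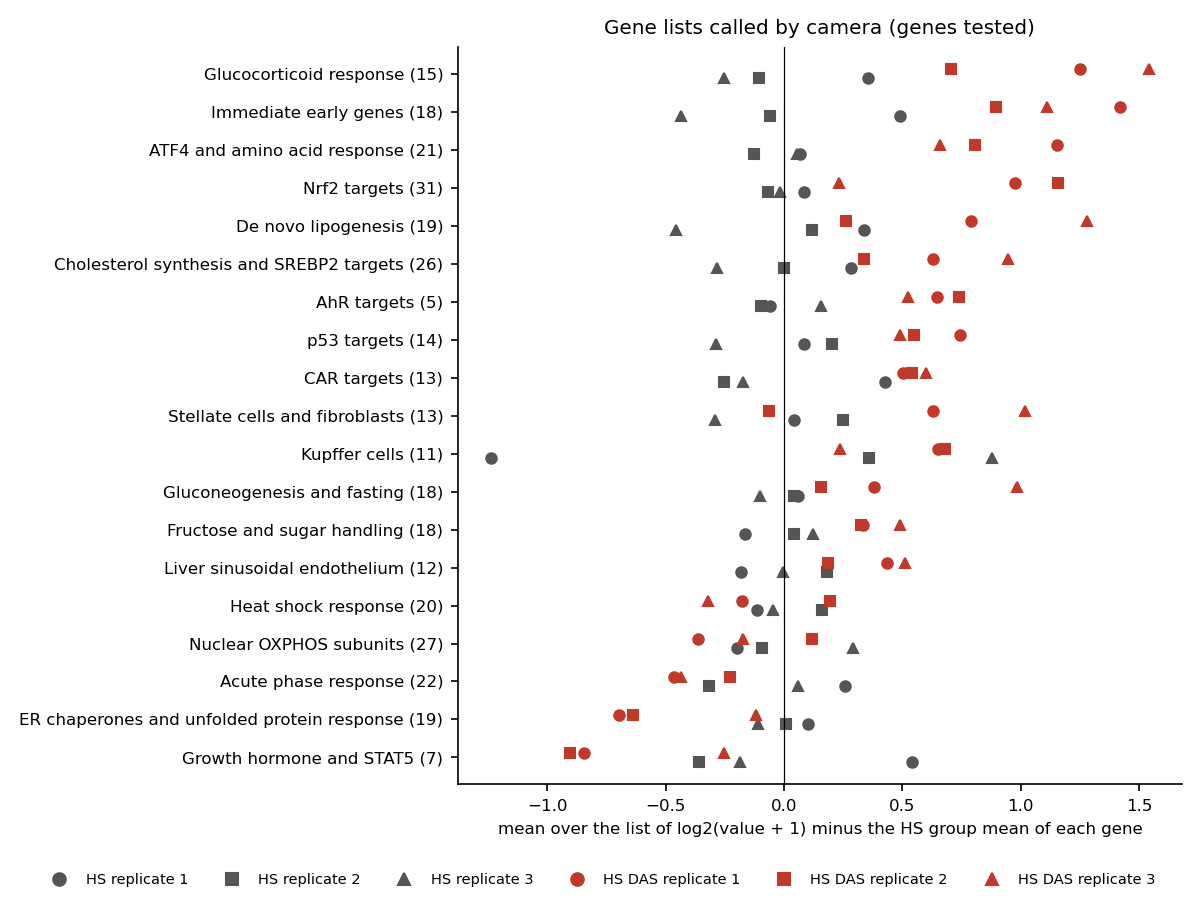
Mean log2(value + 1) of each called gene list in each library, relative to the HS group mean of each gene, so that 0 is the HS average; the number of genes tested stands in brackets and symbols mark the replicate. HS DAS replicate 3 stands at 0.23 for the Nrf2 targets, against 0.98 and 1.16 in the other HS DAS libraries, and HS replicate 1 stands at -1.24 for the Kupffer cell markers.

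The targets of Nrf2, the transcription factor that responds to electrophiles and oxidants, rose as a set (camera, adjusted p = 2.73e-12; adjusted p = 0.337 with an estimated correlation). Of 31 members 28 had a positive log2 difference, the median was 0.51, and 5 passed with a rise when adjusted over the list alone. Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, averaged 6790 ± 2290 normalized counts in HS DAS and 1379 ± 122 in HS (SD, n = 3), a log2 difference of 2.24 (SE 0.28; limma adjusted p = 0.0646). Srxn1, which encodes sulfiredoxin, averaged 1109 ± 223 against 322.1 ± 33.1. Hmox1, haem oxygenase 1, stood at 4019.7, 6254 and 320.2 in the 3 HS DAS libraries and between 108.1 and 155 in HS, a log2 difference of 3.87 (SE 0.95; adjusted p = 0.338). Without HS DAS replicate 3 the limma adjusted p of Hmox1 was 0.00305 and that of Gclc 0.0191. With each library left out in turn they ranged from 0.00305 to 0.896 and from 0.0191 to 0.372. Nqo1, a quinone reductase, averaged 68.8 ± 26.3 against 41.5 ± 1.2, every HS DAS library lying above every HS library (adjusted p = 0.565). Sinusoidal endothelial and stellate cell markers were also called higher, with medians of 0.45 and 0.69 (adjusted p = 0.337 and 0.42 with an estimated correlation). Without HS DAS replicate 3 the stellate median was 0.24 and the camera adjusted p 0.189, in a range of 1.35e-05 to 0.189 over the alternatives.

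Genes of the ATF4 and amino acid response rose as a set (camera, adjusted p = 7.89e-10; adjusted p = 0.217 with an estimated correlation), with 20 of 21 members higher, a median of 0.63 and 5 past the threshold when adjusted over the list alone. Gdf15, a secreted stress-induced protein, averaged 252.1 ± 30.8 normalized counts against 39.2 ± 17.8 (SD, n = 3), and Atf3, a stress-induced transcription factor, 86.6 ± 39.4 against 10.2 ± 1.74 (log2 difference 2.89, SE 0.36, adjusted p = 0.0646). Immediate early genes, which also include Atf3, rose as a set as well (camera, adjusted p = 4.11e-09; adjusted p = 0.239 with an estimated correlation). Of this list 16 of 18 were higher, with a median of 0.87 and 8 past the threshold when adjusted over the list alone. Klf6, a zinc finger transcription factor, averaged 218.2 ± 65.7 against 75.4 ± 7.46. Endoplasmic reticulum chaperones and unfolded protein response genes fell as a set (camera, adjusted p = 8.9e-06; adjusted p = 0.337 with an estimated correlation), 18 of 19 being lower, with a median of -0.44. Only Creld2 passed when adjusted over that list alone. It averaged 266.3 ± 102 in HS DAS and 590.6 ± 85.3 in HS, a log2 difference of -1.20 (SE 0.27; adjusted p = 0.329 over all genes). Xbp1, a transcription factor of the unfolded protein response, averaged 1098 ± 391 against 2078 ± 378. HS DAS replicate 3 stood at -0.12 for this list, close to HS, against -0.70 and -0.64 in the other HS DAS libraries.

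Glucocorticoid-responsive genes rose as a set (camera, adjusted p = 2.74e-07; adjusted p = 0.239 with an estimated correlation), with 14 of 15 higher, a median of 0.88 and 6 past the threshold when adjusted over the list alone. Cdkn1a, an inhibitor of cell cycle kinases that also belongs to the p53 list, averaged 1551 ± 688 normalized counts against 201.2 ± 141 (log2 difference 3.09, SE 0.54, limma adjusted p = 0.187). Mt2, a metallothionein, averaged 4175 ± 2010 against 525.5 ± 685, with HS replicate 1 at 1317 and the other HS libraries at 124.8 and 134.7. Without HS replicate 1 its adjusted p was 0.00723, in a range of 0.00723 to 0.878 with each library left out in turn. The p53 targets rose as a set (camera, adjusted p = 0.00154; adjusted p = 0.337 with an estimated correlation), with 10 of 14 higher and 3 past the threshold when adjusted over the list alone. Their median of 0.46 became 0.20 without HS replicate 3 and 0.19 without HS DAS replicate 1. Genes of gluconeogenesis and fasting rose as a set (camera, adjusted p = 0.019; adjusted p = 0.534 with an estimated correlation), with 12 of 18 higher and 3 past the threshold when adjusted over the list alone. Without HS DAS replicate 3 the median went from 0.32 to 0.07 and the camera adjusted p was 0.251, in a range of 0.00346 to 0.251 over the alternatives. Within that list Igfbp1, a secreted binder of insulin-like growth factors, averaged 4542 ± 2710 against 655.8 ± 37.5 (limma adjusted p = 0.0819, and 0.0299 without HS DAS replicate 3, in a range of 0.0299 to 0.372 with each library left out). Pdk4, which restrains pyruvate dehydrogenase, averaged 367.2 ± 211 against 65.3 ± 39.4. Pck1, the gluconeogenic carboxykinase, averaged 25390 ± 3980 against 30600 ± 2650 (log2 difference -0.28, SE 0.19, adjusted p = 0.736).

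Cholesterol synthesis and SREBP2 target genes rose as a set (camera, adjusted p = 1.96e-10; adjusted p = 0.337 with an estimated correlation). Of 26 members 24 were higher, with a median of 0.66, 0.41 without HS DAS replicate 3, and 7 past the threshold when adjusted over the list alone. Sc5d, a sterol desaturase, averaged 5410 ± 92.3 normalized counts against 2953 ± 200 (SD, n = 3; log2 difference 0.88, SE 0.16, limma adjusted p = 0.187), and Insig1, a sterol-regulated anchor protein of the endoplasmic reticulum, 4290 ± 1850 against 1568 ± 79.1. The de novo lipogenesis list also rose (camera, adjusted p = 5.8e-08; adjusted p = 0.337 with an estimated correlation), with 18 of 19 higher, a median of 0.64 and 3 past the threshold when adjusted over the list alone. That median was 0.40 without HS replicate 3 or without HS DAS replicate 3. The mean of the list overlapped between the groups, at 0.34 in HS replicate 1 and 0.26 in HS DAS replicate 2. Gpam, which starts glycerolipid synthesis, averaged 6152 ± 2310 against 1818 ± 599, and Thrsp 10160 ± 2370 against 3923 ± 1430. Fasn, fatty acid synthase, averaged 14260 ± 9060 against 3890 ± 2190, its groups overlapping (adjusted p = 0.455). Fructose and sugar handling genes rose as a set (camera, adjusted p = 0.019; adjusted p = 0.337 with an estimated correlation; 0.0795 by camera without HS replicate 1, in a range from 0.00342 over the alternatives), with 12 of 18 higher. The median of 0.20 became 0.12 without HS replicate 1 or 2 and 0.09 without HS DAS replicate 3. When adjusted over that list alone 4 passed with a rise and 1 with a fall. Ppp1r3c and Ppp1r3g, regulatory subunits that direct protein phosphatase 1 to glycogen, averaged 950.5 ± 372 against 280.6 ± 153 and 232 ± 170 against 43.5 ± 12.2. Sinusoidal endothelial and stellate cell markers were called higher beside these groups (adjusted p = 0.337 and 0.42 with an estimated correlation).

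Among receptors for foreign compounds, AhR targets rose as a set (camera, adjusted p = 0.00192; adjusted p = 0.239 with an estimated correlation), all 5 tested members being higher and 2 past the threshold when adjusted over the list alone. Tiparp averaged 160.1 ± 52.1 normalized counts against 78.6 ± 10.9, and Cyp1a1, a cytochrome P450 induced through AhR, 28.4 ± 5.18 against 10.6 ± 4.37 (SD, n = 3; limma adjusted p = 0.381). CAR targets rose as a set (camera, adjusted p = 0.00278; adjusted p = 0.337 with an estimated correlation; 0.0661 by camera without HS replicate 2, in a range from 3.26e-05 over the alternatives), with 11 of 13 higher and 0 past the threshold when adjusted over the list alone. The median of 0.37 was 0.64 without HS replicate 1, 0.24 without HS replicate 3 and 0.23 without HS DAS replicate 3. Gadd45b averaged 31.9 ± 13.3 against 8.14 ± 3.94 and Gstt3, a glutathione transferase, 579.7 ± 63.2 against 392.9 ± 73.2. Cyp2b10, a cytochrome P450 induced through CAR, stood at 30.7, 11.5 and 23.1 in HS DAS and at 26.5, 2.2 and 2.4 in HS (adjusted p = 0.618). Cyp2e1 averaged 36420 ± 2710 against 43570 ± 8540 (adjusted p = 0.792). PXR targets were not called (camera, adjusted p = 0.125).

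Genes of hydrogen sulfide and cysteine metabolism were not called as a set (camera, adjusted p = 0.364), with 13 of 19 higher, a median of 0.14 and 0 past the threshold when adjusted over the list alone. That median was 0.08 without HS replicate 2 or without HS DAS replicate 3. The groups overlapped in the enzymes that make hydrogen sulfide from cysteine and its relatives. Cth averaged 1686 ± 621 normalized counts in HS DAS and 1504 ± 425 in HS (SD, n = 3), Cbs 4003 ± 474 against 3473 ± 476 and Mpst 759.4 ± 96.7 against 734.2 ± 90.5, with log2 differences of 0.14 (SE 0.30), 0.21 (SE 0.18) and 0.05 (SE 0.19) and limma adjusted p-values of 0.921, 0.807 and 0.954. The signs for Cth and Mpst turned without HS DAS replicate 2, to -0.14 and -0.04, and that for Mpst also without HS replicate 1, to -0.06. Sqor, the mitochondrial sulfide oxidoreductase, averaged 1070 ± 22.3 against 959.3 ± 147 (adjusted p = 0.842). Ethe1, the persulfide dioxygenase that follows it, averaged 471.5 ± 22.9 against 313.2 ± 34.3, with all 3 HS DAS libraries above all 3 HS libraries and a log2 difference of 0.59 (SE 0.18; adjusted p = 0.408).

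Besides the chaperones, 4 lists fell. Acute phase genes had 19 of 22 members lower and a median of -0.33 (camera, adjusted p = 0.00252; adjusted p = 0.387 with an estimated correlation; 0.0845 by camera without HS replicate 1, in a range of 8.23e-05 to 0.164 over the alternatives). Without HS replicate 1 that median was -0.17. The mean of the list overlapped between the groups, at -0.32 in HS replicate 2 and -0.23 in HS DAS replicate 2. Haptoglobin, Hp, averaged 19120 ± 550 normalized counts against 26440 ± 4680 (SD, n = 3). Cd14, the member with the lowest p, went the other way at 50.5 ± 15 against 22.5 ± 17.8. Growth hormone and STAT5 genes had 5 of 7 lower and a median of -0.70 (camera, adjusted p = 0.019; adjusted p = 0.337 with an estimated correlation). That call was lost without HS replicate 1 (0.079), HS DAS replicate 1 (0.0629) or HS DAS replicate 2 (0.128), in a range of 0.000725 to 0.155 over the alternatives, and the median was -0.39 without HS replicate 1. The mean of that list overlapped between the groups, at -0.357 in HS replicate 2 and -0.255 in HS DAS replicate 3. In that list Igfals averaged 444.8 ± 42.8 against 719.5 ± 36.3 and passed when adjusted over the list alone, and Socs2 averaged 91 ± 78.2 against 230.6 ± 94.3. Nuclear genes of oxidative phosphorylation had 25 of 27 lower and a median of -0.14 (camera, adjusted p = 0.0431; adjusted p = 0.761 with an estimated correlation). That call ended without HS replicate 3 (0.964), HS DAS replicate 1 (0.629) or HS DAS replicate 3 (0.0999) and with the length trend removed (0.398), in a range of 0.00263 to 0.964 over the alternatives. The median was 0.009 without HS replicate 3 and lay between -0.05 and -0.28 with another library left out. The mean of the list was higher in HS DAS replicate 2, at 0.117, than in HS replicates 1 and 2, at -0.2 and -0.092. Cox5b averaged 1101 ± 322 against 1459 ± 234 and Ndufs3 717.2 ± 141 against 858.2 ± 134. The groups overlapped in Cox5b and Ndufs3, as in Cd14 and Socs2. Without HS DAS replicate 1 the log2 difference of Cox5b went from -0.44 to -0.17 and that of Ndufs3 from -0.27 to -0.11. Heat shock genes had 15 of 20 lower and a median of -0.21 (camera, adjusted p = 0.0479; adjusted p = 0.608 with an estimated correlation). That call was lost without HS replicate 2 (0.303), HS DAS replicate 1 (0.204) or HS DAS replicate 3 (0.302), in a range of 0.000328 to 0.303 over the alternatives. It held in only 9 of 19 other settings, and was also lost with upper-quartile scaling, the stricter filter, a pseudocount of 10, the replicate block, no trend, and length or GC removal (0.0522 to 0.0803). The median was -0.12 without HS DAS replicate 1. Of the 5 members that were higher, Hspa1a, the inducible HSP70, chosen after its values were seen, stood at 175.2, 135.5 and 7.2 in HS DAS and averaged 22.3 ± 2.13 in HS (adjusted p = 0.761). Without HS DAS replicate 3 its adjusted p was 0.0427, in a range of 0.0427 to 1 with each library left out. The mean log2 of the list, relative to HS, was highest in HS DAS replicate 2, at 0.19, so the groups overlapped. Ahsa1 and Chordc1, partners of the chaperone HSP90, averaged 601.5 ± 104 against 878.7 ± 140 and 207.6 ± 82.1 against 325 ± 39.8.

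Of the cell type markers, those of sinusoidal endothelium rose as a set, with 10 of 12 higher and a median of 0.45 (camera, adjusted p = 0.0022; adjusted p = 0.337 with an estimated correlation; 0.063 by camera without HS replicate 1, in a range of 0.00025 to 0.0796 over the alternatives). Pecam1, an adhesion molecule of endothelium, averaged 167.5 ± 24.4 normalized counts against 94.8 ± 19.9, and Stab1, a scavenger receptor, 352.1 ± 107 against 218.6 ± 52.8 (SD, n = 3). Stellate cell and fibroblast markers rose as a set, with 11 of 13 higher and a median of 0.69 (camera, adjusted p = 0.00999; adjusted p = 0.42 with an estimated correlation). That call was lost without HS replicate 1 (0.059) or HS DAS replicate 3 (0.189), in a range of 1.35e-05 to 0.189 over the alternatives. The median was 0.33 without HS replicate 3, 0.36 without HS DAS replicate 1 and 0.24 without HS DAS replicate 3. The mean of the list overlapped between the groups, at 0.25 in HS replicate 2 and -0.06 in HS DAS replicate 2. Hgf averaged 80.9 ± 3.73 against 50.1 ± 18.3 and Des 47.7 ± 15.6 against 27.1 ± 2.96. Kupffer cell markers had all 11 higher and a median of 0.44 (camera, adjusted p = 0.0406; adjusted p = 0.731 with an estimated correlation). Without HS replicate 1 the median was -0.17 (0.244), and the call was also lost without HS DAS replicate 1 (0.067) or HS DAS replicate 2 (0.183), in a range of 1.72e-05 to 0.594 over the alternatives. The median was 0.92 without HS replicate 3 and 0.29 without HS DAS replicate 2. Here too the mean of the list overlapped between the groups, and HS replicate 3 had the highest of all libraries, at 0.88. Marco averaged 127.4 ± 118 against 36.7 ± 29.8 and Timd4 57.1 ± 26.3 against 36 ± 25.1. The groups overlapped in Marco and Timd4, as in Stab1 and Des. The log2 difference of Marco went from 1.68 to 0.97 without HS DAS replicate 1, and that of Timd4 from 0.93 to 0.07 without HS replicate 1. Markers of hepatocytes (camera, adjusted p = 0.429), periportal hepatocytes (0.0567), pericentral hepatocytes (0.438), cholangiocytes (0.429) and erythroid cells (0.843) were not called, although the periportal list passed without HS DAS replicate 3 (0.0342, in a range of 0.0342 to 0.197 over the alternatives).

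The remaining lists were not called by camera. The adjusted p-values were 0.27 for NF-kB and chemokine genes, 0.28 for proteasome subunits, 0.295 for cytosolic ribosomal proteins, 0.324 for haem and iron genes and for male-biased liver genes, 0.585 for the cell cycle, 0.594 for PPAR alpha targets, 0.807 for bile acid genes and 0.843 for clock and interferon genes. For PPAR alpha targets the median was -0.04 and the mean 0.22. The list was called higher without HS replicate 1 (median 0.33, adjusted p = 0.0223) and lower without HS replicate 3 (-0.24, 0.0121), in a range of 2.65e-05 to 0.717 over the alternatives. Bile acid genes had a median of -0.07 and a mean of 0.003, and clock genes a median of 0.04 and a mean of -0.004. The ribosomal proteins were called lower without HS replicate 1 (0.00365), HS replicate 2 (0.0276) or HS DAS replicate 2 (0.0121), and higher without HS replicate 3 (0.00502), in a range of 0.00365 to 0.86 over the alternatives. Proteasome subunits were called lower without HS replicate 1 (0.0163) or HS DAS replicate 2 (0.00229), male-biased genes lower without HS replicate 1 (0.00582), and haem and iron genes higher without HS DAS replicate 3 (0.0159). Proteasome subunits were also called lower without both HS replicate 3 and HS DAS replicate 2 (0.0417), and male-biased genes with array weights (0.0488). Over the alternatives these 3 lists ranged from 0.00229 to 0.93, from 0.00582 to 0.962 and from 0.0159 to 0.869.

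The first principal component held 48.9% of the variance and did not separate the groups. HS replicate 3 scored 57.8 and HS DAS replicate 2 21.7, and the other libraries lay between -41.1 and 6.7. The second component, with 21.1% of the variance, placed the HS DAS libraries between 13.8 and 28.1 and the HS libraries between -36.3 and -0.8. Major urinary protein genes took 11.8% of the values in HS replicate 3 and between 2.5% and 6.8% in the others. Without HS replicate 3 and HS DAS replicate 2 together, a choice made after the data were seen, 16 genes passed an adjusted p of 0.05 and 19 lists were called, 17 of them among the 19 called with all libraries.

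**Figure D3:**
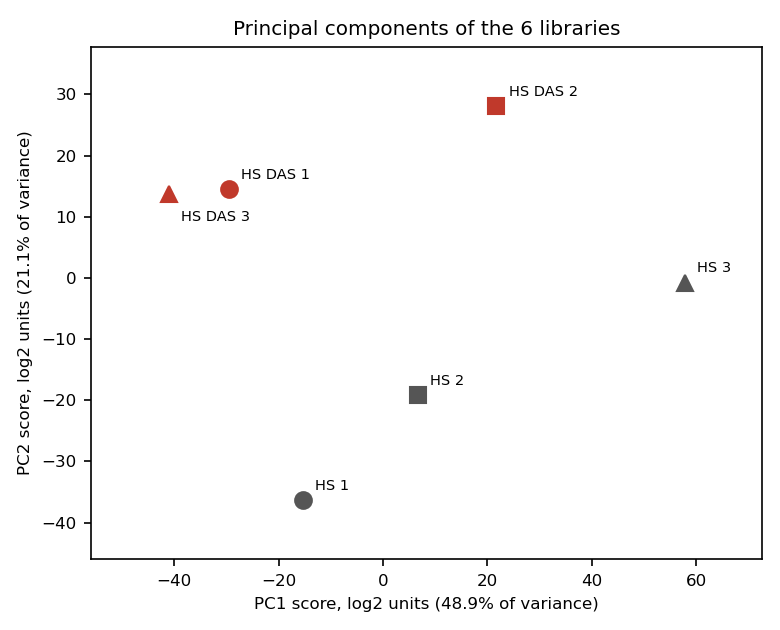
Scores of the 6 libraries on the first and second principal components of log2(value + 1) over 11413 genes, in log2 units, with HS in grey and HS DAS in red. The second component parts the groups, while on the first HS replicate 3 (57.8) and HS DAS replicate 2 (21.7) lie farthest to the right.

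On the mouse build mm10, Chka lies on chromosome 19 from 3851773 to 3894369, Gdf15 on chromosome 8 from 70629393 to 70632456, Srxn1 on chromosome 2 from 152105516 to 152111376, Thbd on chromosome 2 from 148404466 to 148408188 and Trp53inp1 on chromosome 4 from 11156431 to 11174379. Gclc lies on chromosome 9 from 77754535 to 77794485, Hmox1 on chromosome 8 from 75093621 to 75100589, and Atf3 on chromosome 1 from 191170296 to 191218039. All are annotated as protein-coding genes. Of the genes named, Chka, Gpam, Mt2, Des, Ppp1r3g, Arntl, Tef, Usp2 and Ciart overlap annotated antisense transcripts, and others, among them Dbp, Nr1d1, Stab1, Ndufs3 and Ethe1, overlap protein-coding genes of the opposite strand. The library kit keeps strand, but the counting setting is not given in the sources used here, so reads of the opposite strand in these genes cannot be excluded.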

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

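The tests with an adjusted p of 0.10, robust moderation, no trend, array weights, length or GC removal, and without 2 libraries together were chosen after the result was seen. By limma-trend the count of 0 genes at an adjusted p of 0.05 held with equal totals, upper-quartile scaling, no filter, the stricter filter, both pseudocounts, robust moderation, no trend and GC removal; a fold threshold cannot change a count of 0. It became 12 with the length trend removed, 16 without both HS replicate 3 and HS DAS replicate 2, and 9 at an adjusted p of 0.10; the cause was not tested. Array weights, which are estimated from the same values, gave 2868 genes. HS replicate 2 took a weight of 31.3 and the others 0.24 to 1.85, so the HS mean in that fit rests almost wholly on 1 library. Of the HS DAS libraries replicate 1 weighed most, at 1.85. Leaving out 1 library gave 0 to 5 genes: Mt2, Mt1 and Mup16 without HS replicate 1, Dbp without HS DAS replicate 2, and Hmox1, Gclc, Igfbp1, Osgin1 and Hspa1a without HS DAS replicate 3. Mup16 belongs to a family of near-identical genes and is listed at 0 in HS replicate 1 and all HS DAS libraries. The 9 genes under an adjusted p of 0.10 kept their sign in every setting, and of these 9 all passed 0.05 with the length trend removed and 5 without both libraries. At an adjusted p of 0.10, 0 genes passed with the replicate block, with no trend, and without HS replicate 3 or HS DAS replicate 1. Genes at an unadjusted p under 0.05 were 1033 with all libraries, 1752 without both those libraries, and from 574 (HS DAS replicate 1) to 1620 (HS DAS replicate 2) with 1 left out. Against the 19 called lists, an estimated correlation gave 0, fry in one direction 0 and fry in either direction 8. Those 8 include the clock list (fry adjusted p = 0.0177), which camera did not call. The others were ATF4 and immediate early genes (0.000711 each), p53 (0.00168), AhR and fructose (0.00456 each), and Nrf2 and glucocorticoid (0.0365 each). Cholesterol synthesis and chaperones (0.0575 each) and lipogenesis (0.134) did not pass fry in either direction. Camera with an estimated correlation and fry each ask another question or allow for correlation between genes. Correlation alone does not account for every loss. The ATF4 and AhR lists had estimated correlations of 0.04 and -0.06 and were lost too (camera with these, adjusted p = 0.217 and 0.239). With an estimated correlation 0 lists were called in every setting. That test was not run on simulated data, so whether it could call a list with 3 libraries per group is not known. Leaving out 1 library gave 15 to 20 lists, and of the 19 between 13 and 18 were still called. The targets of Nrf2, AhR and ATF4, cholesterol synthesis, lipogenesis, glucocorticoid response, immediate early genes and chaperones were called in all 19 other settings of scaling, filter, model and libraries. Of named genes, Cth turned to -0.143 without HS DAS replicate 2 and ranged up to 0.361 with 1 library left out. Mpst turned to -0.12 with array weights, -0.018 with GC removal and between -0.055 and 0.146 when 1 library was left out. Nr1d1 turned to -0.19 with array weights and -0.097 without HS replicate 3, in a range up to 0.494. The median of PPAR alpha targets was -0.368 without both libraries and from -0.243 without HS replicate 3 to 0.333 without HS replicate 1, that of ribosomal proteins from -0.327 without HS replicate 1 to 0.209 without HS replicate 3, and that of Kupffer cell markers from -0.174 without HS replicate 1 to 0.922 without HS replicate 3; the cause was not tested. With the replicate block 0 genes passed an adjusted p of 0.05 and 18 lists were called, heat shock (0.0724, in a range of 0.000328 to 0.303) being lost. Calls also ended with array weights for the gluconeogenesis, acute phase, p53, growth hormone, Kupffer, endothelial and stellate lists, with the stricter filter for CAR, heat shock, oxidative phosphorylation and Kupffer, with no trend for the last 3 of these, with no filter for Kupffer, and without both libraries for CAR and growth hormone. Same-numbered libraries had deviations correlated at 0.31, -0.27 and -0.39, and no HS library correlated best with its own number alone (replicate 1 did as well with HS DAS replicate 3), so the numbers were not read as pairs. The quasi-likelihood, DESeq2 and voom tests and TMM scaling need counts and were not run, and the RLE scaling is the one the values already carry. With 3 libraries per group and 8440000 to 11470000 reads each, changes of 1 log2 unit were mostly missed in simulated data (23.9% recovered). The simulated noise was independent between genes, so larger changes may also be missed in the real data. There Hmox1 and Cdkn1a, with log2 differences of 3.87 and 3.09, did not pass (limma adjusted p = 0.338 and 0.187).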

Other observations

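The tests of chance for the number of genes at an adjusted p of 0.05, of depth, of clock times, and of a library without DAS or with a smaller response were chosen after the values they use had been seen.

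Genes of the circadian clock moved in both directions. The list as a whole was not called by camera (adjusted p = 0.843), but when adjusted over the list alone 4 of its 20 members passed with a higher value in HS DAS and 5 with a lower one, and fry called it for change in either direction (adjusted p = 0.0177). Dbp, a clock output transcription factor, averaged 137.7 ± 69.9 normalized counts in HS DAS and 733.6 ± 40 in HS (SD, n = 3), a log2 difference of -2.52 (SE 0.33; limma adjusted p = 0.0756 over all genes, 0.0194 without HS DAS replicate 2, in a range of 0.0194 to 0.395 with each library left out). Tef averaged 700.6 ± 231 against 1426 ± 54.7, Per3 44.3 ± 27.1 against 132.8 ± 36.2 and Usp2 171.7 ± 100 against 426.6 ± 65.9. Arntl, whose protein drives the clock together with CLOCK, averaged 156.2 ± 40.1 against 35.3 ± 9.36, Nfil3 515 ± 112 against 204.5 ± 15.2 and Npas2 47 ± 56.8 against 2.83 ± 2.45. Nr1d1 averaged 947.4 ± 284 against 804.7 ± 315 and Ciart 108.2 ± 31.5 against 90.6 ± 16.3, both with overlapping groups.

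With the length trend removed, the median absolute log2 difference of Dbp, Tef, Per3, Usp2, Arntl, Nfil3 and Npas2 was 1.96, against 1.81 before, which argues against the length trend as the cause of the clock pattern. Those 7 genes were chosen after their values were seen; over the whole list the groups did not overlap in 8 of 20 genes, against 15.1% of all tested genes and 10% by chance. That the groups were killed at different clock times cannot be told apart from an effect of DAS: fry gave an adjusted p of 0.0177 for the list, and the labels give no times of death. A candidate explanation is thus either a shift in sampling time or a response to the gavage or to DAS within 3 h. Equal sampling times in both groups would remove the first. Times that differed between the groups would leave the explanations inseparable in these libraries.

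HS DAS replicate 3 had 320.2 normalized counts of Hmox1 and the other HS DAS libraries 4019.7 and 6254, a log2 distance of 3.96 that was 3.89 with the length trend removed, which argues against that trend. Over the 37 genes past an unadjusted p of 0.001 in a fit without this library, it showed a median 0.62 of the change of the other HS DAS libraries (quartiles 0.14 and 1.07, 32 genes in the same direction), while the same measure, each over genes selected anew without the library in question (16 to 60), gave 0.91 and 0.56 for HS DAS replicates 1 and 2 and 0.35, 0.20 and -0.06 for the HS libraries. An animal that was gavaged but missed the compound cannot be told apart from this, since the gavage or the sampling time could give a change shared with the other HS DAS libraries, and the mean of Nrf2 targets was 0.23 against 0.98 and 1.16. A uniformly smaller response, as from a lower absorbed dose, would leave no list further from HS than in the other HS DAS libraries, yet this library's mean was 1.28 log2 units above HS in lipogenesis (0.79 and 0.26 in replicates 1 and 2), 1.54 in glucocorticoid (1.25 and 0.71), 0.98 in gluconeogenesis (0.38 and 0.16) and 0.95 in cholesterol genes (0.63 and 0.34). Such a response still cannot be told apart: 27% of the 37 genes changed more in this library than in the mean of the others, past a bound of 25% first set against it, but 1 library gives no spread for that share; over the 17 lists called without this library, taking it to vary like the others, camera called 3 as changed further in it and 4 as changed less with the preset correlation, and 0 with an estimated one (lowest adjusted p for a further change = 0.593), and limma called 0 of 703 genes as changed further (for Igfbp1, at 7667.3 against 2988.1 and 2971.7, adjusted p = 0.772); no biological explanation was tested, since the labels name none that sets this animal apart.

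HS replicate 3 and HS DAS replicate 2 had the 2 highest scores on the first principal component, 57.8 and 21.7, though HS DAS replicate 2 was nearer to HS replicate 2, at 6.7. Without 21 major urinary protein genes and with totals rescaled it held 48.5% of the variance, against 48.9% with them, which argues against these genes as the cause. Depth does not set these 2 apart, as 1 of the other libraries had an implied depth between their 8560000 and 9430000 reads, and HS replicate 2 was shallower. Component loadings followed transcript length across genes (Spearman's rho = -0.48, genes not being independent replicates), and after removal of the length trend the component held 43.2% of the variance with HS replicate 3 at 50.0, HS DAS replicate 2 at 15.2 and HS replicate 2 at 10.1, so length may be part of the pattern, and how far cannot be told apart from what remains. No biological explanation was tested, since the groups do not part these libraries.

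The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes at an adjusted p of 0.05, a count that all 10 splits reached, and the highest other gave 1. It gave 1033 genes at an unadjusted p under 0.05, where 2 of the 10 splits, the real one included, gave as many; the other gave 3127. That other split, of HS replicate 1 with HS DAS replicates 1 and 3 against the rest, follows the first principal component and points to a structure of the samples other than the groups. For lists called by camera the real split gave 19, a number reached by 1 split, itself, with 18 as the highest other. Every split that mixed the groups called lists as well, at least 4. The number of lists called at the preset correlation thus does not by itself set the grouping by treatment apart. Each mixed split still held part of the treatment difference, since its sides had unequal numbers of HS and HS DAS libraries. Which lists the mixed splits called, and in which direction, was not compared.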
